A study of Sus scrofa with 12 samples.

How the data were processed

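Early and hatched blastocysts of the pig (Sus scrofa), collected in vivo 5 and 5.5 days after insemination, were compared on 2 microarray designs. Each design was used for 6 arrays, and each array carried labelled RNA of both stages, 1 in Cy3 and the other in Cy5. In both array sets 3 arrays had the hatched stage in Cy5 and 3 had the early stage in Cy5. Arrays are named here by the stage in Cy5 and by a replicate number given in the order of deposition, which pairs no arrays. Per the labels' protocols, total RNA was extracted with a PicoPure kit, amplified in 2 rounds with T7 RNA polymerase (RiboAmp HS Plus), and labelled chemically with the ULS system for Agilent slides. The labels do not say which arrays share RNA extracts, or whether the replicates came from separate litters, so p-values measure the spread between these arrays, which may be technical.

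The deposited value is 1 log ratio of the 2 channels per probe and array. The unit was taken as log2 on both array sets, because the second holds single values at -12.7 and 12.2, too wide for log10. This argues against log10 only, and a natural log was not tested. The base was carried over to the first array set, whose values reached 5.35. Counts at 2-fold rest on it. What the authors did to make these log2 values before they were deposited is not stated in the labels: the log base, scanner, background correction, normalization and direction of the ratio are not given in the sources used here, and no channel intensities were used. Every array's median lay between -0.0061 and 0.0105, no value was missing, and the deposited values were used without further centring.

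The values appeared to have been turned to 1 direction before deposition. The arrays with hatched blastocyst in Cy5 are written to 9 decimals and those with early blastocyst in Cy5 to 6 significant digits, and the part of the ratio shared by all arrays correlated more closely between the array sets than the part that follows the dyes. The deposited values were therefore averaged as they stand. Which stage is the numerator is not stated and was not settled, so signed values are given as the positive or the negative side of the deposited ratio, with no statement of which stage was higher.

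Probes were named from GEO's platform annotation. Accessions and symbols were updated through a table of RefSeq genes of the assembly Sscrofa11.1, used for names only, and no coordinates are given because no build is named for the arrays. On the first array set 18121 of 43794 probes had 1 gene symbol, 0 had several and 25673 were unnamed. There, 2656 of 4740 probes with an accession matched the table, 576 LOC symbols and 241 synonyms were updated, and 14648 symbols were kept. On the second array set 10290 of 45220 probes had 1 symbol, 0 had several and 34930 were unnamed. There, 6055 of 10193 probes with an accession matched, 173 LOC symbols and 70 synonyms were updated, and 3992 symbols were kept. The unnamed probes of the second array set may include control spots. Probes of 1 symbol were averaged per array, which gave 11912 genes on the first array set and 4531 on the second, of which 3326 and 2394 had several probes.

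Each array set was fitted alone with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with a stage effect and a dye term. The stage effect was tested 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors beside log2 ratios are the fit's standard errors over 6 arrays. In this fit each array is 1 sample. Gene lists, 27 in number and fixed before the data were examined, were tested with camera at its preset correlation of 0.01, adjusted over the lists of that array set, with an estimated correlation and fry as alternatives. Lists needed at least 5 measured genes. The lists cover lineages of the blastocyst, junctions, transport, proteases, steroid and cholesterol synthesis, lipids, energy metabolism, ribosomal proteins, replication, mitosis, apoptosis, stress, chromatin, oocyte genes, 3 signalling groups, the cytoskeleton, and other cells that a flushed embryo could carry (oviduct and uterus, blood, cumulus and sperm).

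Genes named in the text follow a rule fixed before the data were examined. It takes, per array set, the 10 largest ratios each way among genes past the threshold that lay on the same side on all 6 arrays. Over both array sets it takes the 10 largest mean ratios each way among genes called on the same side in both. It adds up to 4 members of each list with the smallest p-values, and always CDX2, POU5F1, NANOG, SOX2, GATA3, GATA4, GATA6, KRT8, KRT18, TEAD4, ATP1B1, AQP3 and CDH1 where measured. LOC symbols and hypothetical proteins were passed over.

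The gene test was tested on simulated data with 200 changed genes in each of 10 runs. With independent arrays it recovered 96.1% of changes of 1 and 70.6% of changes of 0.5 on the log2 scale among the 11912 genes of the first array set, with 5.07% false calls among all calls. For the 4531 genes of the second array set these shares were 96.7%, 73.8% and 5.49%. In further runs simulated arrays shared noise in pairs, with the same correlation for every pair and gene. It was 0.424 for the first array set and 0.510 for the second, the consensus over the real genes. The false share with each array as 1 sample was then 15.2% for the first array set and 15.8% for the second, and 5.65% and 4.88% with the pairs as a random block. With the pairs averaged, the fit recovered in these arrays 87.1% of changes of 1 and 13.7% of changes of 0.5 for the first array set, and 92.3% and 31% for the second. Each simulated change had the same size in every pair. The real ratios differed in size between pairs. The real residuals also correlated unevenly, from 0.374 to 0.720 over the pairs of the first array set and from 0.471 to 0.703 on the second. All these shares, including the false shares, therefore need not hold for the real arrays. A shift of 0.25 put into the mitosis list was called in 10 of 10 runs for either array set. The simulated genes had noise independent of each other, so these runs do not test list calls where members correlate. On the real arrays the estimated correlation of the mitosis list was 0.354 on the first array set and 0.307 on the second.

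Alternatives fixed before the data were examined were the dye term, pairs of arrays by title order, slide, centring, scaling, quantile normalization, a filter on spread, the shrinkage, the threshold, the probe summary and each array left out in turn. After the data were seen, pairs of arrays that the residuals pointed to, the fit without the second of these pairs, named probes only, and the reading of the values as Cy5 over Cy3 were added. In both array sets the residuals correlated most closely within 3 pairs of opposite dye. These are hatched in Cy5 replicate 1 with early in Cy5 replicate 2 (r = 0.637 on the first and 0.539 on the second array set, across probes), early in Cy5 replicate 1 with hatched in Cy5 replicate 2 (0.720 and 0.703), and the replicates numbered 3 (0.374 and 0.471). They are named pairs 1, 2 and 3, and pair 2 is called the second pair. With a dye term in the fit, residuals sum to 0 over the arrays of either orientation. This pushes correlations within a dye orientation below 0, so the residuals favour pairs of opposite dye. Before the fit, the values of early in Cy5 replicates 2 and 3 correlated most closely (0.731 and 0.670), and those of pair 2 at 0.210 and 0.262. Whether the pairs share RNA is not known.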

Results

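Pig embryos at the early blastocyst stage (5 days after insemination) and at the hatched blastocyst stage (5.5 days), when the embryo has left the zona pellucida, were hybridised directly against each other. The comparison asks which transcripts differ in abundance between the stages. It was run on 2 array designs, the first array set with 43794 probes and the second with 45220, each with 6 arrays, 3 in either dye orientation. The deposited log2 ratios had standard deviations from 0.301 to 0.462 on the first array set and from 0.364 to 0.512 on the second. The number of arrays limits the precision. The labels do not settle which stage is the numerator, so each ratio below is placed on the positive or the negative side with no statement of which stage was higher.

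On the first array set the largest positive ratio belonged to ASNS, which makes asparagine, with a log2 ratio of 2.90 ± 0.30 (SE, n = 6 arrays; limma adjusted p = 0.00400). It was followed by APOA1, the main protein of high-density lipoprotein, at 2.32 ± 0.22, and by the glutathione peroxidase gene GPX1 at 2.10 ± 0.22. BLNK, an adaptor of B cell receptor signalling, lay at 1.99 ± 0.30, and NPC1, which carries cholesterol out of lysosomes, at 1.97 ± 0.22. Among genes without a LOC symbol, which were passed over here and below, the largest negative ratio was that of the cytokine gene IL6, at -2.63 ± 0.19 (adjusted p = 0.00142). ATP6V0D2, a subunit of the vacuolar proton pump, lay at -2.57 ± 0.25.

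Other positive ratios among the 10 largest were those of the glutamate dehydrogenase gene GLUD1 (1.90), the calcium-binding protein gene S100A11 (1.89), the cytidine deaminase gene CDA (1.76), PAPSS2, which makes the sulfate donor PAPS (1.76), and the galactosyltransferase gene B4GALT5 (1.74). On the negative side they were SFT2D2 (-2.07), PMEPA1, a target of TGF-beta (-1.92), EIF2AK4, the kinase GCN2 that senses uncharged tRNA (-1.89), the transcription factor gene BATF3 (-1.56), NUCB2 (-1.53), the cell death gene BAD (-1.52), the RNA methyltransferase gene FTSJ1 (-1.47) and TMEM59 (-1.33). All 20 genes lay on 1 side on all 6 arrays, which the rule for naming them requires, and each was measured by 1 probe. Leaving out 1 array ended the call of 8 of them. The highest adjusted p was that without early in Cy5 replicate 3 for GLUD1 (0.175), TMEM59 (0.102), S100A11 (0.0771), CDA (0.0701) and BLNK (0.0660), without early in Cy5 replicate 2 for PAPSS2 (0.0513), and without hatched in Cy5 replicate 1 for NUCB2 (0.0642) and BATF3 (0.0551).

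**Figure D1:**
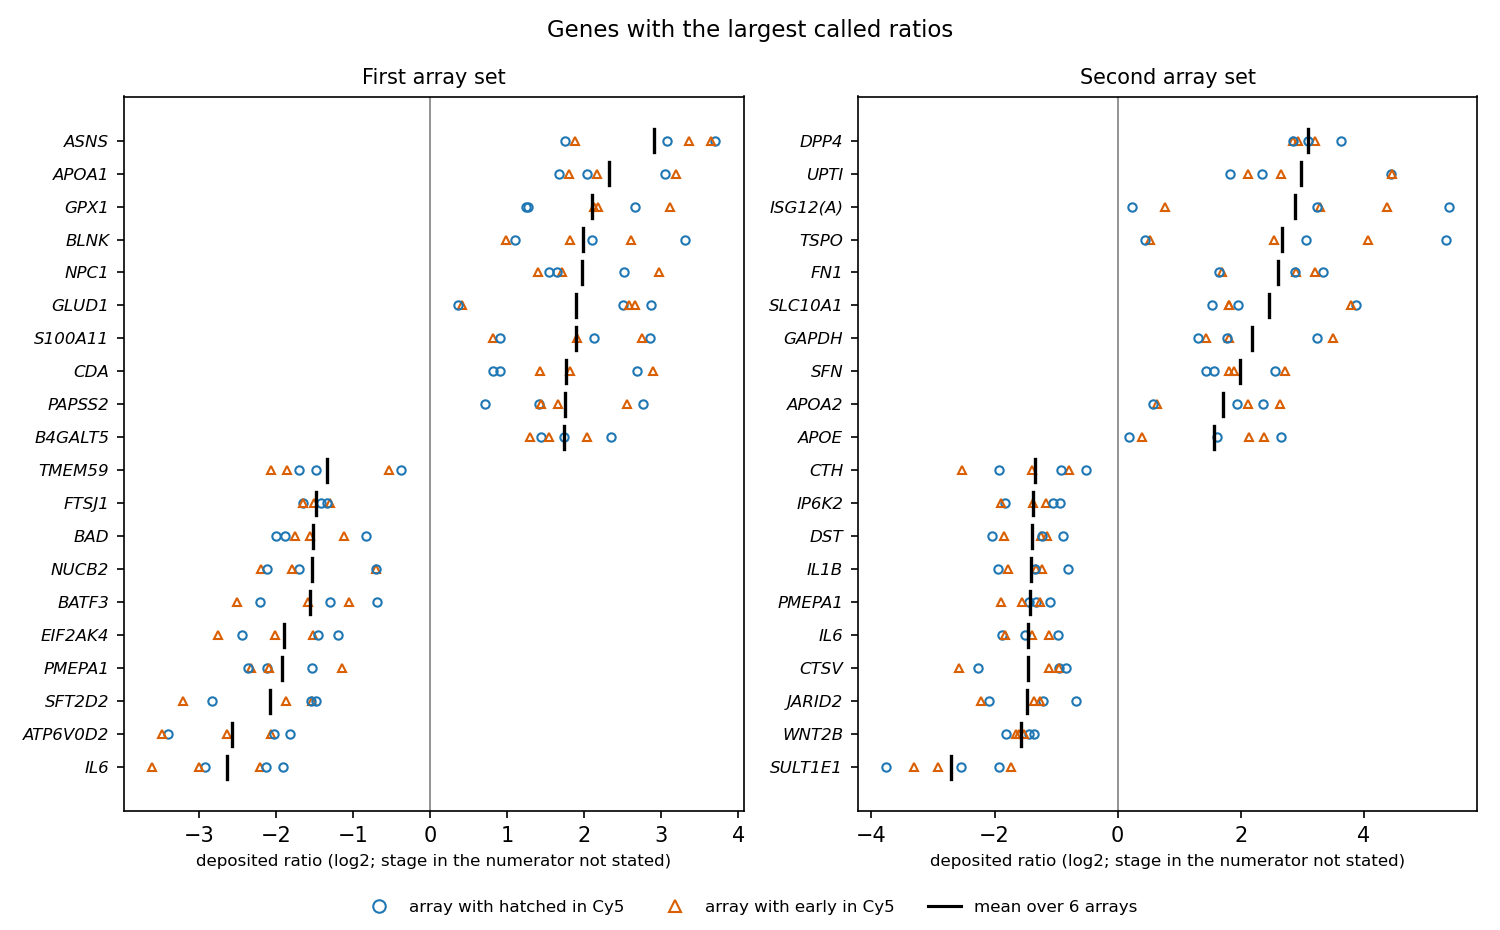
Deposited log2 ratio (horizontal axis) of the 10 largest positive and 10 largest negative called genes of each array set, LOC symbols passed over, with 1 point per array (circles, hatched blastocyst in Cy5; triangles, early blastocyst in Cy5) and a bar at the mean over 6 arrays. ASNS lies at a mean of 2.90 on the first array set and DPP4 at 3.09 on the second. Every array of each gene shown lies on the same side of 0, since only such genes were taken.

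In all, 566 of 11912 genes passed the threshold on the first array set, 283 on either side, 132 of them by at least 2-fold, and 505 lay on the same side on all 6 arrays. Of 43794 probes 2032 passed, 948 on the positive and 1084 on the negative side. The count depended on which arrays count as separate samples: 451 genes passed with the residual pairs as a random block and 0 when limma was fitted to the 3 pair averages (smallest adjusted p = 0.0752; 1270 genes at an unadjusted p under 0.05), against 1169 without the second pair. It was 243 within the slide that held 4 arrays, and 234, 197, 229 and 258 without hatched in Cy5 replicate 1, early in Cy5 replicate 2, early in Cy5 replicate 3 and hatched in Cy5 replicate 3.

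Of 18 measured hypoblast genes 5 were called positive and 0 negative on the first array set, with 7 positive when adjusted over the list alone, and 12 had a ratio above 0. The called genes included the laminin gene LAMB1 (0.79 ± 0.06), the apolipoprotein gene APOE (0.67 ± 0.06) and the collagen gene COL4A1 (0.45 ± 0.05), besides APOA1. The list was called positive (mean log2 ratio 0.31, median 0.0996, positive on 6 of 6 arrays; camera adjusted p = 0.000222), with an adjusted p = 0.476 with an estimated correlation. GATA6, a regulator of this lineage, lay at -0.06 ± 0.13 (adjusted p = 0.866).

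The members called in the lists of cell division genes lay on the negative side. For mitosis 2 of 33 measured members were called, both negative (3 adjusted over the list alone), and 6 had a ratio above 0. The called genes were the spindle gene TPX2 (-0.56 ± 0.08) and the securin gene PTTG1 (-0.88 ± 0.14). The mean of the list was -0.23 (positive on 1 of 6 arrays; adjusted p = 0.000108, and adjusted p = 0.611 with an estimated correlation). It was -0.08 and 0.12 on the second pair and between -0.55 and -0.13 on the other 4 arrays. For DNA replication 3 of 26 were called, again negative (3 adjusted over the list alone), and 9 had a ratio above 0. The called genes were RFC5 (-0.63 ± 0.08), LIG1 (-0.44 ± 0.07) and POLE2 (-0.59 ± 0.11). That list had a mean of -0.17 and was positive on 0 of 6 arrays (adjusted p = 0.00533, and adjusted p = 0.476 with an estimated correlation). It was -0.08 and -0.07 on the second pair and between -0.27 and -0.20 on the other 4 arrays.

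Both ribosomal lists were also called negative. Of 39 mitochondrial ribosomal proteins 4 were called negative and 0 positive (8 and 3 adjusted over the list alone), among them MRPL44 (-0.72 ± 0.08) and MRPL22 (-0.72 ± 0.12), with a list mean of -0.16 on the negative side on 5 of 6 arrays (adjusted p = 0.00533, and adjusted p = 0.611 with an estimated correlation). It was -0.02 and 0.02 on the second pair and between -0.34 and -0.15 on the other 4. Of 48 cytosolic ribosomal proteins 4 were called negative and 1 positive (5 and 1 adjusted over the list alone), with a mean of -0.10 and 2 of 6 arrays positive. The negative ones were RPL10A (-0.45 ± 0.08), RPL35A (-0.39 ± 0.07), RPS18 (-0.38 ± 0.07) and RPS13 (-0.35 ± 0.07). With the pairs as a random block the calls of RPL35A (adjusted p = 0.0624), RPS18 (0.0792) and RPS13 (0.0536) ended. The cytosolic list had an adjusted p = 0.0379, and adjusted p = 0.611 with an estimated correlation. Its call ended without hatched in Cy5 replicate 1 (adjusted p = 0.0535) or 2 (0.0724) and without early in Cy5 replicate 2 (0.110) or 3 (0.0621).

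The list of oxidative stress and heat shock genes was called positive (mean 0.14, positive on 5 of 6 arrays; adjusted p = 0.0434, and adjusted p = 0.476 with an estimated correlation). Of 38 members 6 were called positive and 1 negative (6 and 3 adjusted over the list alone). The positive ones included GPX1, the chaperone gene HSP90AA1 (0.80 ± 0.07) and the peroxiredoxin gene PRDX5 (0.34 ± 0.05), whereas PRDX4, the peroxiredoxin of the endoplasmic reticulum, lay at -1.10 ± 0.07 (adjusted p = 0.000777). The call ended without early in Cy5 replicate 1 (adjusted p = 0.146), hatched in Cy5 replicate 2 (0.166) or early in Cy5 replicate 3 (0.0621), with the pairs averaged (0.0637), and without the second pair, which is the first 2 of these arrays (0.504). The second pair also stood apart for oxidative phosphorylation, a list that was not called (adjusted p = 0.151). Its mean was 0.20 and 0.32 on these arrays and between -0.55 and -0.12 on the other 4. The list had an adjusted p of 1.21e-05 without both, 0.00154 without early in Cy5 replicate 1 and 0.0175 without hatched in Cy5 replicate 2, all at the preset correlation, and over all 6 arrays an adjusted p = 0.664 with an estimated correlation. Of its 38 measured members 3 were called positive and 0 negative (4 and 1 adjusted over the list alone), ATP5G1 (0.59 ± 0.06), ATP5D (0.96 ± 0.13) and CYCS (1.28 ± 0.26), on the other side from the list mean of -0.14.

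Lineage genes were mixed. Of 23 trophectoderm genes 4 were called positive and 0 negative (5 and 1 adjusted over the list alone), namely GATA2 (1.06 ± 0.15), the galectin gene LGALS3 (1.09 ± 0.17) and the keratin genes KRT8 (0.76 ± 0.14) and KRT18 (0.50 ± 0.11), but the list was not called (adjusted p = 0.102). KRT18 had an adjusted p of 0.0782 with the pairs as a random block. Ratios of CDX2 (0.26 ± 0.07), GATA3 (0.04 ± 0.11), TEAD4 (-0.03 ± 0.09), POU5F1 (0.34 ± 0.08) and SOX2 (0.05 ± 0.08) did not pass. Of 22 genes of the inner cell mass and epiblast 1 was called, SALL4 at -0.34 ± 0.07 (adjusted p = 0.126 with the pairs as a random block), and KLF4 lay at -0.37 ± 0.13 without passing.

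Among the other lists of the first array set, none of which was called (smallest adjusted p = 0.102), single members passed. The tight junction genes CLDN4 (-0.86 ± 0.08) and CGN (0.49 ± 0.09) lay on opposite sides, each by 1 of its 2 probes: those of CLDN4 lay at -1.71 and -0.0074 and those of CGN at -0.16 and 1.14. The junction list had an adjusted p of 0.0127 without early in Cy5 replicate 1 and 0.0397 without hatched in Cy5 replicate 2 at the preset correlation, and over all 6 arrays an adjusted p = 0.655 with an estimated correlation. The ion transport regulator gene FXYD4 lay at 1.02 ± 0.08, the sodium pump gene ATP1B1 at -0.38 ± 0.07, and the water channel gene AQP3 at -0.19 ± 0.06 without passing. Positive ratios were called for the sterol demethylase gene CYP51 (1.51 ± 0.10), the fatty acid synthase gene FASN (1.02 ± 0.09), the retinoid-binding protein gene CRABP2 (0.40 ± 0.07), the prostaglandin E synthase gene PTGES (0.75 ± 0.15) and the glycolytic genes GAPDH (0.89 ± 0.13) and TPI1 (0.64 ± 0.10). The 2 probes each of CYP51 (0.26 and 2.75), FASN (0.10 and 1.95) and GAPDH (0.05 and 1.72) differed, so those means rest largely on 1 probe. Negative ratios were called for the fatty acid carrier gene FABP5 (-0.97 ± 0.18), the cell death gene BID (-0.67 ± 0.11), the heterochromatin gene CBX3 (-0.63 ± 0.10), SMAD1 (-0.37 ± 0.08), CYR61 (-1.06 ± 0.22), and the oocyte genes ZP4, a zona pellucida protein (-0.36 ± 0.06), and MOS (-0.68 ± 0.12). Of 38 cytoskeletal genes 6 were called positive and 2 negative (10 and 8 adjusted over the list alone), among them TAGLN2 (0.50 ± 0.06), ANXA5 (0.69 ± 0.08) and ANXA2 (-0.72 ± 0.08). With the pairs as a random block the calls of CGN (adjusted p = 0.0721), MOS (0.0516) and SMAD1 (0.139) ended, and 67 of the 76 called genes named under the rule were still called. No member passed in 6 lists: proteases, FGF and MAPK signalling, oviduct and uterine epithelium, blood and immune cells, cumulus and granulosa cells, and sperm.

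On the second array set DPP4, a membrane peptidase, had the largest positive ratio, 3.09 ± 0.11 (n = 6 arrays; adjusted p = 4.2e-05). UPTI, a uterine plasmin and trypsin inhibitor, lay at 2.97 ± 0.40, the interferon-inducible gene ISG12(A) at 2.88 ± 0.69, TSPO, a cholesterol-binding protein of the outer mitochondrial membrane, at 2.66 ± 0.65, and the fibronectin gene FN1 at 2.61 ± 0.26. The largest negative ratio was that of the estrogen sulfotransferase gene SULT1E1, at -2.70 ± 0.27 (adjusted p = 0.00215). Among genes without a LOC symbol, WNT2B, a Wnt ligand, followed at -1.56 ± 0.07.

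The remaining positive genes among the 10 largest were the bile acid transporter gene SLC10A1 (2.46), GAPDH (2.18), SFN, which encodes 14-3-3 sigma (1.99), and the apolipoprotein genes APOA2 (1.71) and APOE (1.56). On the negative side they were JARID2, a cofactor of Polycomb repressive complexes (-1.47), the cathepsin gene CTSV (-1.45), IL6 (-1.45), PMEPA1 (-1.43), the cytokine gene IL1B (-1.41), the cytoskeletal linker gene DST (-1.40), IP6K2 (-1.37) and CTH, which makes cysteine from cystathionine (-1.35). The 3 probes of IL6 ranged from -2.69 to -0.41. On the second pair ISG12(A) lay at 0.77 and 0.23 and TSPO at 0.52 and 0.44, against at least 3.24 and 2.55 on each of the other 4 arrays. Without hatched in Cy5 replicate 1 their ratios were 2.27 and 2.07, and without hatched in Cy5 replicate 2 they were 3.56 and 3.29. Leaving out 1 array ended the calls of TSPO (adjusted p up to 0.141), ISG12(A) (0.135) and APOE (0.121), highest without early in Cy5 replicate 2, and of APOA2 (0.0579) and CTH (0.0550), highest without hatched in Cy5 replicate 3.

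Of 4531 genes 498 passed, 239 on the positive and 259 on the negative side, 77 by at least 2-fold, and 460 lay on the same side on all 6 arrays. Of 45220 probes 2766 passed, 1128 positive and 1638 negative. The gene count was 373 with the residual pairs as a random block and 4 when limma was fitted to the 3 pair averages (DPP4, WNT2B, PAQR8 and AKR1A1, the last pair named after their values were seen; 725 genes at an unadjusted p under 0.05), against 785 without the second pair. It was 210 within the slide that held 4 arrays, and 255, 261, 284 and 289 without hatched in Cy5 replicate 1, early in Cy5 replicate 2, early in Cy5 replicate 3 and hatched in Cy5 replicate 3.

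Called mitosis genes lay on the negative side on the second array set as well. Of 18 measured members 4 were called negative and 0 positive (4 and 0 adjusted over the list alone): PTTG1 (-1.02 ± 0.07), the cyclin gene CCNB1 (-0.73 ± 0.13), KIFC1 (-0.43 ± 0.07) and AURKA (-0.42 ± 0.10; adjusted p = 0.0600 with the pairs as a random block). The list mean was -0.31 and lay on the negative side on 6 of 6 arrays (adjusted p = 0.00318, and adjusted p = 0.573 with an estimated correlation). It was -0.16 and -0.14 on the second pair and between -0.63 and -0.19 on the other 4. The list of DNA replication genes, with 8 measured, had a mean of -0.01 and was not called (adjusted p = 0.956).

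Cholesterol synthesis was the list called positive. Of 11 measured members 4 were called positive and 0 negative (4 and 0 adjusted over the list alone), CYP51 (0.74 ± 0.07), SQLE (0.65 ± 0.10), FDPS (0.32 ± 0.06) and PMVK (0.33 ± 0.06; adjusted p = 0.0640 with the pairs as a random block). The mean of 0.24 was positive on 6 of 6 arrays (adjusted p = 0.00965, and adjusted p = 0.573 with an estimated correlation). The call ended without the second pair (adjusted p = 0.119) and without early in Cy5 replicate 1 alone (0.0553). The 4 probes of CYP51 ranged from -0.0014 to 2.70.

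The hypoblast list had a mean of 0.44 on the second array set and was not called (adjusted p = 0.153). Of 13 measured members 4 were called positive, among them FN1, APOA1 (1.54 ± 0.24) and FLRT3 (0.42 ± 0.09), and GATA6 was called negative (-0.72 ± 0.15). Of 17 trophectoderm genes 3 were called positive and 3 negative (5 and 3 adjusted over the list alone), with GATA2 at 1.30 ± 0.20, LGALS3 at 1.10 ± 0.18, KRT8 at 0.72 ± 0.16 and the endocytic adaptor gene DAB2 at -1.12 ± 0.16. Ratios of KRT18 (0.67 ± 0.19), TEAD4 (0.12 ± 0.12), POU5F1 (0.09 ± 0.32), NANOG (-0.06 ± 0.14), SOX2 (0.16 ± 0.11), GATA4 (0.07 ± 0.09), CDH1 (-0.26 ± 0.16) and AQP3 (0.01 ± 0.06) did not pass. Of 16 genes of the inner cell mass and epiblast DPPA5 (0.89 ± 0.10) and LIN28A (0.36 ± 0.08; adjusted p = 0.0850 with the pairs as a random block) were called positive and KLF4 negative (-1.28 ± 0.17), although the 7 probes of KLF4 ranged from -2.56 to 0.62.

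In the other lists of the second array set, none of which was called (smallest adjusted p = 0.153), ATP1B1 lay at -0.81 ± 0.10 and the water channel gene AQP1 at -0.81 ± 0.10. Of 17 genes of glycolysis and glucose uptake 5 were called positive and 1 negative (6 and 2 adjusted over the list alone), with the glucose transporter gene SLC2A8 at 1.51 ± 0.15, TKT at 0.64 ± 0.07 and the monocarboxylate transporter gene SLC16A1 at -0.73 ± 0.09. In the list of steroid and prostaglandin synthesis and maternal recognition, the prostaglandin E synthase gene PTGES (0.89 ± 0.06) and FDX1, which passes electrons to steroid-making enzymes (0.86 ± 0.08), were called positive and the cytokine gene IL1B negative (-1.41 ± 0.15). The peroxiredoxin genes PRDX4 (-1.04 ± 0.07) and PRDX5 (0.60 ± 0.06) lay on opposite sides, and GPX1 lay at 1.42 ± 0.14. Of 20 oxidative phosphorylation genes 3 were called positive, ATP5G1 (0.87 ± 0.11), ATP5B (0.46 ± 0.06) and COX5B (0.42 ± 0.07), and 1 negative, NDUFA4 (-0.47 ± 0.09), with 4 and 4 adjusted over the list alone. The mean of that list was -0.14; it was 0.19 and 0.23 on the second pair and between -0.48 and -0.22 on the other 4 arrays (adjusted p = 0.654, and 0.0320 without the second pair, both at the preset correlation, and over all 6 arrays an adjusted p = 0.947 with an estimated correlation). The lysosomal protease gene CTSD lay at 0.99 ± 0.09, the tight junction gene CLDN6 at 1.03 ± 0.16, the catenin gene CTNNA1 at -0.70 ± 0.10, FABP5 at -1.26 ± 0.16, FASN at 0.66 ± 0.09, RPS4X at -0.65 ± 0.08, MRPS10 at -0.60 ± 0.08 and BID at -0.39 ± 0.06. The zona genes ZP4 (-1.23 ± 0.09) and ZP2 (-0.47 ± 0.09), the DNA demethylase gene TET1 (-0.81 ± 0.19), the receptor genes ACVR1 (-0.41 ± 0.08) and FZD3 (-0.61 ± 0.07) and ANXA2 (-0.60 ± 0.12) were called negative, and JUN (0.55 ± 0.08) positive. AMH (0.35 ± 0.08) and STAR (0.27 ± 0.07) were called among cumulus and granulosa genes, with adjusted p-values of 0.0645 and 0.106 with the pairs as a random block, under which 79 of the 90 called genes named under the rule were still called. No member passed in the lists of DNA replication, oviduct and uterine epithelium, blood and immune cells, and sperm.

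**Figure D2:**
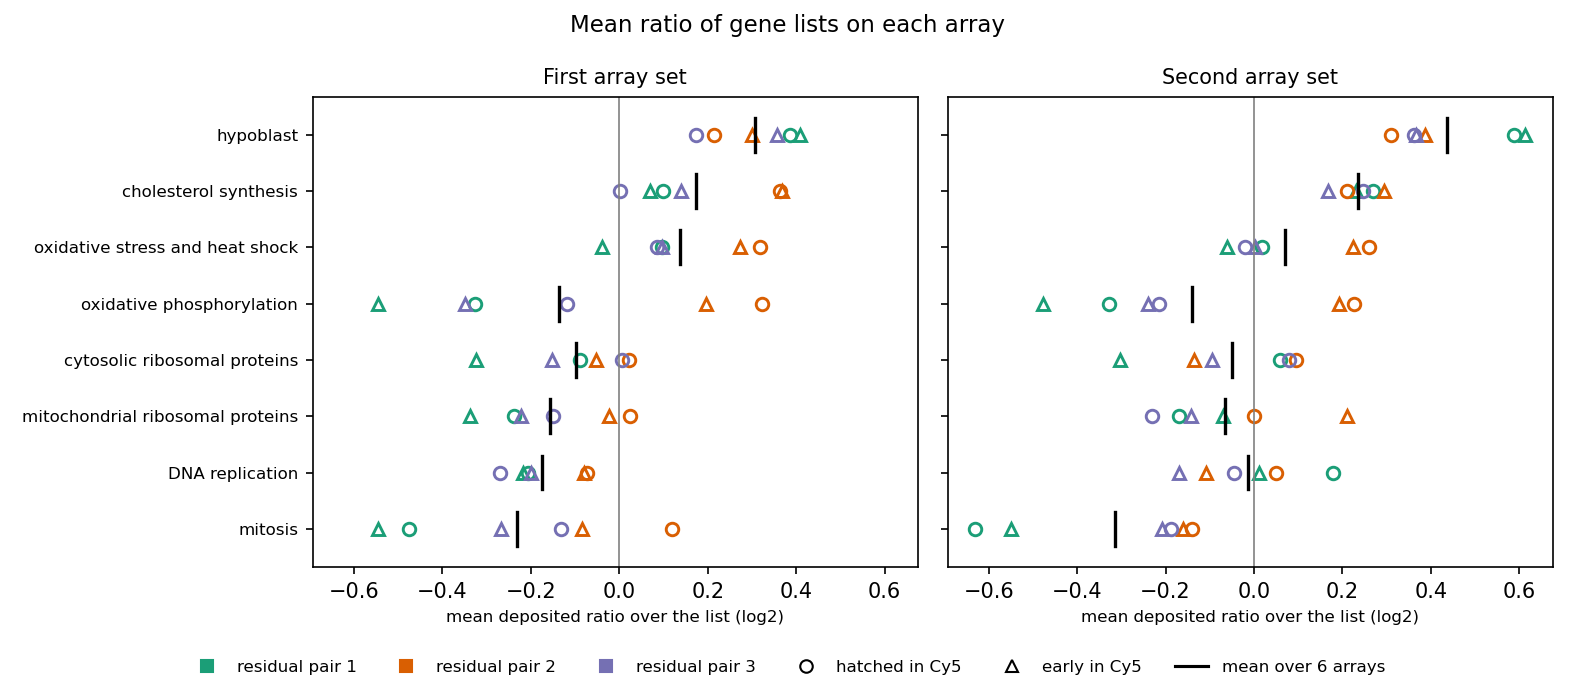
Mean log2 ratio (horizontal axis) of 8 gene lists on each of 6 arrays per array set, with circles for hatched and triangles for early blastocyst in Cy5, colours for the 3 pairs of arrays that the residuals pointed to, and a bar at the mean. For oxidative phosphorylation the second pair lies at 0.20 and 0.32 on the first array set and 0.19 and 0.23 on the second, while the other 4 arrays lie below 0 on both.

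Across the 27 lists, camera called 2 positive and 4 negative on the first array set and 1 positive and 1 negative on the second. With an estimated correlation none was called on either (smallest adjusted p = 0.476 and 0.573). The self-contained test fry called 4 and 11, of which 2 and 2 were among the lists that camera called. On the first array set the shared lists were hypoblast and DNA replication, and mitosis had a fry adjusted p of 0.174. Fry called ion and water transport on opposite sides, with a mean of 0.13 on the first array set (fry adjusted p = 0.00712) and -0.11 on the second (0.0125). Oocyte-expressed genes were called by fry with negative means on both, -0.08 (fry adjusted p = 0.000406) and -0.16 (0.0115). Among uncalled lists of the first array set, mean, median and camera's direction differed in sign for inner cell mass and epiblast, proteases, glycolysis, chromatin, and FGF and MAPK signalling. On the second array set this held for ion and water transport, DNA replication, cytoskeleton, oviduct and uterine epithelium, blood and immune cells, and cumulus and granulosa cells.

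The array sets, which differ in probes, were compared across the 3817 genes measured on both. APOA1 had the largest mean ratio of the genes called on the same side in both, 1.93, followed by DPP4 (1.89), GPX1 (1.76), APOA2 (1.61), BLNK (1.56), GAPDH (1.53), NPC1 (1.53), S100A11 (1.38), GLUD1 (1.35) and the saposin precursor gene PSAP (1.22). On the negative side, with LOC symbols again passed over, IL6 came first, with a mean of -2.04, followed by PMEPA1 (-1.68), the peptide transporter gene SLC15A1 (-1.13), FABP5 (-1.12), PRDX4 (-1.07), PGRMC1 (-1.03), JARID2 (-0.99), IP6K2 (-0.98), TMEM59 (-0.98) and PTTG1 (-0.95).

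Of the 235 and 427 called genes among these 3817, 110 were called on both array sets. They included 58 positive on both, 50 negative on both and 2 on opposite sides, where independent lists would share 6.97, 6.10 and 13.2. With the pairs as a random block 88 of the 108 on the same side were still called on both. Pearson's r of the ratios across genes was 0.489 and Spearman's rho 0.395, and r was 0.318 over the 1209 genes with a single probe on both. Genes are not independent replicates, and the labels do not say whether the array sets had the same RNA, so no p-value is given.

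**Figure D3:**
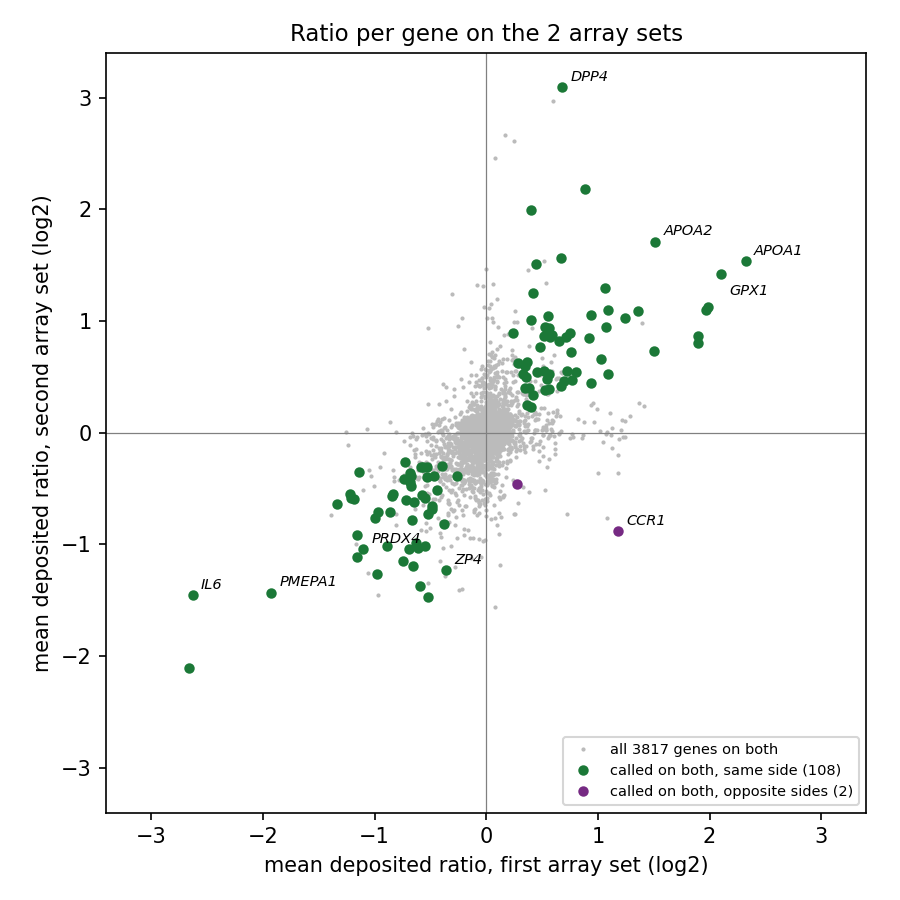
Mean log2 ratio over 6 arrays per gene on the first array set (horizontal axis) and the second (vertical axis), for 3817 genes (grey), the 108 called on both on the same side (green) and the 2 called on opposite sides (purple). IL6 lies at -2.63 and -1.45, and DPP4 at 0.68 and 3.09.

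Probes of 1 gene did not always lie on the same side. Of 205 called genes with several probes on the first array set, 60 had probes on both sides of 0, and of 331 on the second, 95. They included CGN, SLC2A8, ATP5G1 and DPP4 on the first array set, and KLF4, FLRT3, CYP51, SQLE, SLC16A1, FZD3, AMH and STAR on the second. In others a probe close to 0 stood beside a larger one, among them COL4A1, LIG1, POLE2 and ANXA2 on the first array set, and ATP1B1, AQP1, PMVK, FASN, KIFC1, BID, ZP2, ACVR1, BLNK and GLUD1 on the second. The mean of DPP4 on the first array set, 0.68 ± 0.05, came from 4 probes that ranged from -0.10 to 2.71. JARID2, with -0.52 ± 0.11 there, had 3 probes between -1.46 and -0.00027.

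The dye term was called for 1327 probes on the first array set and 3 on the second, and for 114 genes and 0 genes (limma; 648 genes at an unadjusted p under 0.05 on the second). On the first array set the probe count was 282 without hatched in Cy5 replicate 1, 4 without early in Cy5 replicate 1, and 0 without any other single array (10279 probes at an unadjusted p under 0.05 with all 6). On the second it was 48 without early in Cy5 replicate 1, 3 without hatched in Cy5 replicate 2 and 0 without any other (6958 probes at an unadjusted p under 0.05 with all 6).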

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

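The tests of explanations in this part were chosen after the results were seen, and what the splits would show was written after their counts were known. The rule for single arrays far from the others was set beforehand. Over 275 named gene values, 54 list means and 2 sets of standard deviations, the gap of the most distant of the 6 arrays, as a share of the range, was above Dixon's 95% critical value in 5, 0 and 0 cases. Chance gives about 1 in 20. On the first array set these were PLAU (0.649, hatched in Cy5 replicate 3 at 0.10 against values of -0.38 to -0.21), PRSS8 (0.731), ANLN (0.681, hatched in Cy5 replicate 2 at 0.08) and VCAN (0.692). On the second it was S100A12 (0.626). None of these 5 gene values was called.

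The chemokine receptor gene CCR1 was called positive on the first array set (1.18 ± 0.21, 6 of 6 arrays; limma adjusted p = 0.0235) and negative on the second (-0.88 ± 0.06, 0 of 6 arrays positive), a difference of -2.06. PRKAA2, a catalytic subunit of AMP-activated protein kinase, lay at 0.28 ± 0.06 and -0.46 ± 0.07, a difference of -0.73, and its 3 probes on the first array set ranged from -0.36 to 1.15 (adjusted p = 0.116 there with the pairs as a random block). They were named after their values were seen, and the differences were not tested.

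A first pattern is the part of the ratio that all 6 arrays share, from which the calls come. Dye bias in values that were never turned would make it agree no better between the array sets than the part that follows the dyes. Its correlation was higher by 0.309 (95% bootstrap interval over genes 0.253 to 0.363), which argues against that explanation. Genes are not independent replicates, though, so the interval is too narrow, and the array sets may share RNA. The same comparison was a reason for averaging the values as they stand, so it is no separate check of that choice. That swap arrays of 1 RNA pair were counted as separate samples stays open: 451 and 373 genes passed with the pairs as a random block, but 0 and 4 with the pairs averaged.

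A second pattern is the second pair, whose arrays stood apart on both array sets. Called genes of the first array set had a mean ratio along their direction of 0.54 on this pair, against 0.85 and 0.77 on pairs 1 and 3, and those of the second array set 0.51 against 0.81 and 0.66. Dye bias would push the arrays of the pair, which have opposite dyes, apart, but on the second array set, where the pair can be taken from the residuals of the first alone, their residuals correlated at 0.746 across genes. Faults of probes or spots would not repeat across array designs, and the departure of the pair from the other 4 arrays correlated between the array sets at 0.403. That departure also holds the ratios of the other 4 arrays, which by themselves correlated between the array sets at 0.460. It therefore does not decide against such faults. Different embryos, their exact age, or RNA amplification stay open as well, since the labels name no litter or extract, and no biological explanation was tested.

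The 6 arrays part 3 and 3 in 10 ways, too few for a share under 0.05, and these splits treat the arrays as exchangeable although residuals correlated within the pairs. The real split was the 1 split with as many calls: 2032 probes and 566 genes on the first array set, against 0 and 0 at the highest of the others, and 2766 probes and 498 genes on the second, against 499 and 1.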

How the results depend on the processing

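Of the 3 pairs by title order, named before the data were examined, the replicates numbered 3 were also paired by the residuals and the other 2 pairs were not. Alternatives with pairs by residual correlation, without the second pair, with named probes only, with the values read as Cy5 over Cy3 and with the dye term in the agreement were chosen after seeing the data. Averaged in pairs by title order, 3995 and 4188 probes passed on the first and second array set, and 1234 genes on the first. As a random block these pairs gave 889 genes on the first. Residuals within the other 2 pairs correlated at -0.545 and -0.541 on the first array set and -0.479 and -0.427 on the second. Averaging arrays with such residuals cancels part of their spread. With a separate dye term for each slide in place of the common one, 3561 probes and 1068 genes passed on the first array set. That fit takes out no difference between slides in the stage effect. Within the slide with 4 arrays, 1218 and 1222 probes and 243 and 210 genes passed. Without eBayes shrinkage these counts were 21, 136, 59 and 100. Averaged in pairs by residual correlation they were 1, 41, 0 and 4, and without the second pair 4264, 5448, 1169 and 785, of which 465 and 413 genes were among the 566 and 498. Read as Cy5 over Cy3, 1327 and 3 probes and 114 and 0 genes passed. At 2-fold 713, 851, 132 and 77 passed, and at an adjusted p under 0.01, 589, 1066, 162 and 191. Among named probes only, 872 and 1010 passed, as fewer probes were tested. With an estimated correlation 0 and 0 lists were called, and fry called 11 on the second array set. Agreement of the array sets was 0.318 over genes with a single probe and 0.180 for the dye term. Where no cause is given, the cause was not tested.

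With each array left out in turn, 679 to 2443 and 1307 to 3348 probes, 197 to 611 and 255 to 578 genes, 0 to 282 and 0 to 48 dye probes, and 4 to 7 and 1 to 2 lists were called, and agreement ranged from 0.460 to 0.515. Of 76 named called genes on the first array set, 34, 9, 38, 11, 33 and 32 lost the call without hatched in Cy5 replicate 1, early in Cy5 replicates 1 and 2, hatched in Cy5 replicate 2, early in Cy5 replicate 3 and hatched in Cy5 replicate 3; of 90 on the second these were 30, 7, 27, 6, 27 and 21, and 0 changed side. Without the second pair 4 uncalled ratios changed side: GATA6 (0.157) and TEAD4 (0.0926) on the first array set, POU5F1 (-0.0577) and AQP9 (-0.00896) on the second. Leaving out 1 array also turned uncalled ratios. On the first array set SOX2 fell as low as -0.0166 and GATA3 -0.0299, and GATA6 rose as high as 0.0636 and TEAD4 0.0310. Named genes were also compared with no dye term, centring, scaling, the probe median and title pairs averaged. Residual pairs averaged or as a random block, and the fit without the second pair, were added. Over these settings 1917 values kept side and call, counting uncalled ones that stayed uncalled, 224 lost a call and 55 gained one. Of the losses, 164 came from averaging the residual pairs. Counts with no dye term, centring, scaling, quantile normalization, the spread filter, robust eBayes and the residual pairs as a random block stayed within 1.5 times.

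A minimum of 4 arrays moves nothing, since no value was missing, and the slide with 2 arrays leaves no residual degree of freedom. Gene means on the slides correlated at 0.794 and 0.843. Residual pairs 1 and 2 each had arrays on both slides, so these correlations may set the same RNA against itself. Averages of the pairs correlated at 0.229 (1 and 2), 0.278 (2 and 3) and 0.670 (3 and 1) on the first array set. On the second array set these were 0.427, 0.363 and 0.725. The deposited sign as it stands is what was used, and genes in place of probes are reported as gene counts. Without channel intensities, signal over background limits the ratios of weak probes to an unknown degree.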

Other observations

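The tests in this part were chosen after the results were seen. ASNS, the largest positive ratio of the first array set, is induced when amino acids are short, and NPC1 and PSAP, called on both array sets, act in lysosomes. A list of 25 measured genes of the amino acid response and serine synthesis, written without ASNS and CTH, had 3 members called positive and 0 negative on the first array set and a mean of 0.20. On the second, with 14 measured, 4 were called positive and 0 negative, with a mean of 0.24. Camera, adjusted over these 2 lists on both array sets, gave adjusted p-values of 0.000596 and 0.00308 at the preset correlation, and adjusted p = 0.0447 and 0.0701 with an estimated correlation, so the call was lost on the second array set. A list of 31 lysosomal genes without PSAP, NPC1 and LGMN had 7 called positive and 2 negative on the first array set (mean 0.14), and with 19 measured, 4 and 1 on the second (mean 0.15), with adjusted p-values of 0.00298 and 0.00925, and adjusted p = 0.0447 and 0.0633 with an estimated correlation, again lost on the second. The lists were written after the largest genes were seen and lack genes of these pathways on the negative side: EIF2AK4 (-1.89 on the first array set) and CTH (-1.35 on the second) for the amino acid response, and ATP6V0D2 (-2.57 on the first) and CTSV (-1.45 on the second) for lysosomes. Whether either group lies on the positive side as a whole is therefore left open.

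The direction of the ratio is open to a hypothesis from lineage genes. Hypoblast genes appear as the embryo matures and oocyte transcripts are lost, so hatched blastocyst may be the numerator if the former are positive. Called members were 5 positive and 0 negative for hypoblast and 0 and 2 for oocyte genes on the first array set (2-sided Fisher's exact p = 0.0476), and 4 and 1 against 0 and 2 on the second (p = 0.143). GATA6, negative on the second array set, is the exception. Each p is the smallest that its counts can give, and the test used called members of the lists that prompted it, so it decides nothing and the direction stays open.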
